A study of Mus musculus with 24 samples.

How the data were processed

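RNA sequencing was analysed in 20 libraries of mouse ventral prostate organoids, which are epithelial cultures grown in a gel of basement membrane proteins (Matrigel). Per the labels' protocols, the organoids came from a mouse of 4 months, 3000 single cells were seeded in each 30 µL Matrigel dome, and the RNA of 1 dome gave 1 library. Barcoded complementary DNA was pooled after template switching, amplified in 12 cycles of PCR and fragmented with a transposase, and paired reads of 40 bases were sequenced. The labels give 2 organoid clones as biological replicates of each genotype and 5 domes per clone as technical replicates. Whether the clones of 1 genotype came from separate mice is not given in the sources used here, so p-values measure the spread between these clones or domes. The genotypes are named Tmprss2-fl/fl-ERG, called control by the submitters, and Tmprss2-ERG, called T-ERG here. The 4 whole-genome libraries of the series were not analysed here.

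The deposited values are log2(FPKM + 1), that is, fragments scaled to transcript length and to the mapped fragments of the library, on a log2 scale after adding 1. The scale was checked on the values, since 100% of the deposited log2 cells came back as an FPKM with 2 decimals (within 0.001 hundredths). Per the submitters' processing notes, RSEM 1.3.0, which estimates expression from reads shared between transcripts, and DESeq2 were used with genome build mm10. For the RNA libraries, the role of each tool, the aligner and the annotation are not given in the sources used here. The aligner BWA 0.7.12 and build mm9 are named for the whole-genome libraries only. Each library had its own column among 54838 mouse Ensembl genes, and 2321 of these carried no symbol. In 2 T-ERG columns the header gave the same number, so both were used as T-ERG libraries without a number. Both belong to clone 2, because the samples of that genotype left without a column were all of clone 2, and they are called unnumbered libraries a and b.

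The FPKM values summed to between 728255 and 794589 per library, and 14621 to 15457 genes were above 0. FPKM does not carry read counts, so the absolute depth is unknown. A relative depth was instead estimated from 65 to 97 genes per library that were above 0 in only a few libraries. Each such log2 FPKM was set against the gene's median over the libraries where it was above 0. Libraries with higher values were taken as shallower, which assumes that these values stand for few fragments. The estimates ran from 0.818 to 1.16, so the deepest library had an estimated 1.42 times the depth of the shallowest. Genes with an FPKM of at least 1 in at least 5 libraries were tested, which left 12899 genes. No library was a copy of another, since the correlations between domes of the same clone reached at most 0.970 over tested genes.

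Before the data were examined, the clone was fixed as the replicate of the genotype comparison, because the genotype differs only between clones. The 5 libraries of each clone were averaged on the log2 scale, and T-ERG was compared with control on 4 clone means with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend. All p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The 2 clones of each genotype were compared with the same test on 5 against 5 single libraries, and clones are named clone 1 and clone 2 after the labels. Differences are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. On simulated data with 12899 genes, the genotype test recovered 0% of changes of 1 log2 unit, 37.3% of changes of 2 and 81.8% of changes of 4. The simulation drew the spread between clones separately for each gene. These shares therefore may not carry over to data in which genes vary together between clones. In the data, Krt16 and Them5, with differences of 4.15 and 4.00 log2 units, did not pass. The clone test recovered 85.1% of changes of 1 log2 unit in control and 77.6% in T-ERG, also over 12899 genes.

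A total of 26 gene lists were fixed before the data were examined, and 21 had at least 5 tested members. These were tested with camera from limma, with a preset correlation between genes of 0.01, and again with a correlation estimated for each list. The genes named in the genotype comparison follow a rule that was also fixed at that point. It takes Erg, Tmprss2 and Rad21 in any case, then 24 genes by size among those past the threshold, filled with the genes of smallest p whose clone means did not overlap where fewer passed, and then for each list the members past the threshold or, with none, the member with the largest difference. This gave 50 genes, of which some are not reported. Predicted genes and pseudogenes were left out of the middle part. Other list members and the genes named between clones were chosen after their values were seen. Coordinates are 1-based on GRCm38.p6, the assembly of mm10, from a RefSeq gene table in which 12058 of the 12899 tested genes matched by symbol.

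Alternatives were a looser and a stricter filter, pseudocounts of 0.1 and 5, quantile normalization, median centring, other variance priors, all 20 libraries with the clone as a random block, all 20 libraries as independent, blocks of clone, title and dome numbers, and leaving out each replicate. The median differences of the other groupings of the 4 clones were added after the data were seen. The same numbers were also tested for whether they pair the libraries. No reads were counted again, and no count model was used, because the deposited values are not counts.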

Results

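The series title places RAD21, a subunit of the cohesin ring that holds sister chromatids together, in the progression of prostate cancer. The RNA libraries compare organoids of the genotype named Tmprss2-ERG with organoids of the control genotype, named Tmprss2-fl/fl-ERG. Tmprss2 is an androgen-regulated serine protease gene of the prostate epithelium, and ERG is a transcription factor of the ETS family. Both names hold Tmprss2 and ERG, so they do not show that control carries an unmodified Tmprss2 locus. There were 10 libraries per genotype, made of 5 domes from each of 2 clones. Libraries had between 11829 and 12184 genes at an FPKM of 1 or more. Their estimated relative depths lay between 0.818 and 1.16, a ratio of 1.42 between the deepest and the shallowest. Over tested genes, domes of the same clone correlated with a median of 0.965, domes of the other clone of the same genotype with 0.937 and domes of the other genotype with 0.930. These correlations are across genes, which are not independent replicates. The first principal component held 29.8% of the variance and the second 15.2%.

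**Figure D1:**
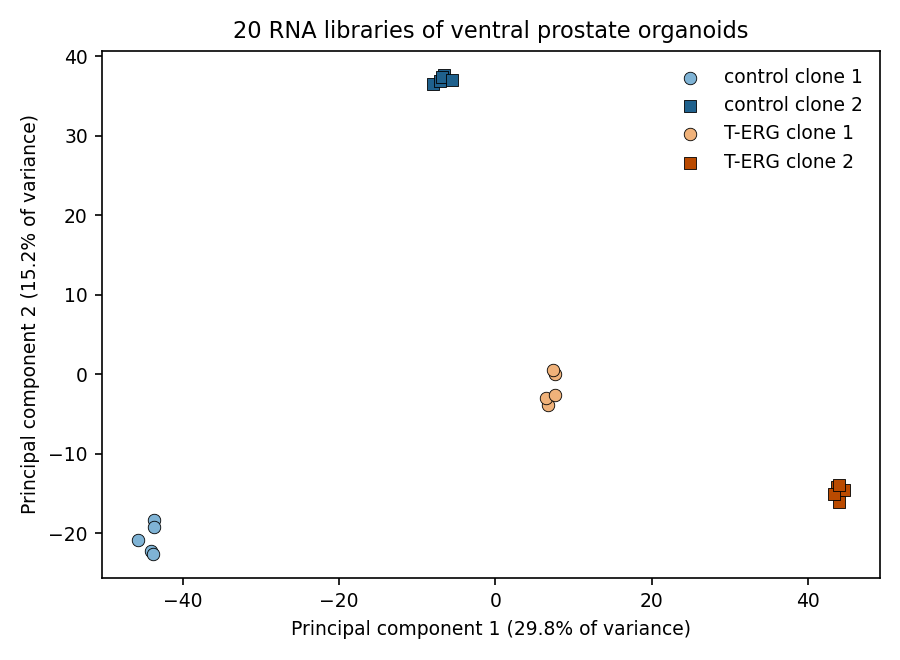
First and second principal components of the 20 libraries, in units of the component scores, with 1 point per dome and colour and shape by genotype and clone. The 4 clones form separate groups, and along the first component they lie in the order control clone 1, control clone 2, T-ERG clone 1 and T-ERG clone 2.

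The mouse Erg gene (ENSMUSG00000040732, chromosome 16, 95359169 to 95586600) was low in both genotypes. It ranged from 0.32 to 2.23 FPKM in the control libraries and from 0.54 to 3.17 FPKM in the T-ERG libraries, with a difference of 0.08 ± 0.28 log2 units (SE, 2 clones per genotype, limma adjusted p = 0.925). The values therefore did not separate the genotypes by mouse Erg. The table lists mouse genes only, so a transcript of another species or an engineered sequence would not appear under its own name, and the labels do not state which ERG sequence the allele carries. Tmprss2 (ENSMUSG00000000385, chromosome 16, 97564682 to 97659541) had a mean of 98.4 FPKM in control and 43.7 FPKM in T-ERG. All 10 T-ERG libraries, at 32.3 to 57.2 FPKM, lay below all 10 control libraries, at 85.2 to 107.4 FPKM. The difference was -1.17 ± 0.18 log2 units and did not pass the threshold (limma adjusted p = 0.506). Rad21 (ENSMUSG00000022314, chromosome 15, 51962604 to 51993538) was at 51.7 FPKM in control and 52.3 FPKM in T-ERG, a difference of 0.01 ± 0.15 log2 units (limma adjusted p = 0.978, 95% interval -0.37 to 0.40).

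In the comparison of T-ERG with control, Krt16, Fabp5 and Gjb2 were among the genes with the smallest p that were higher in T-ERG, and Tspan8 and Igfbp3 among those that were lower. Krt16, a keratin of stressed and fast-growing epidermis, had 130.3 FPKM in control and 2448 FPKM in T-ERG, a difference of 4.15 ± 0.43 log2 units (SE over 4 clone means). Fabp5, the epidermal fatty acid-binding protein, had 245 and 2496 FPKM, a difference of 3.23 ± 0.44, and is uncertain because processed copies of it may share its reads. Gjb2, a connexin of gap junctions, was at 67.0 FPKM in control and 404 FPKM in T-ERG, a difference of 2.59 ± 0.29. Tspan8, a tetraspanin of epithelial cell surfaces, had 174 and 30.4 FPKM, a difference of -2.46 ± 0.22, and Igfbp3, a binding protein of insulin-like growth factors, had 271 and 51.6 FPKM, a difference of -2.42 ± 0.32. No gene passed the threshold in limma on 4 clone means, where the smallest adjusted p was 0.281, and 1089 of 12899 genes (8.44%) had an unadjusted p below 0.05. With all 20 libraries and the clone as a random block, limma called 1398 genes, 674 higher and 724 lower in T-ERG. On simulated data that fit called 476 unchanged genes and is therefore not used for calls.

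**Figure D2:**
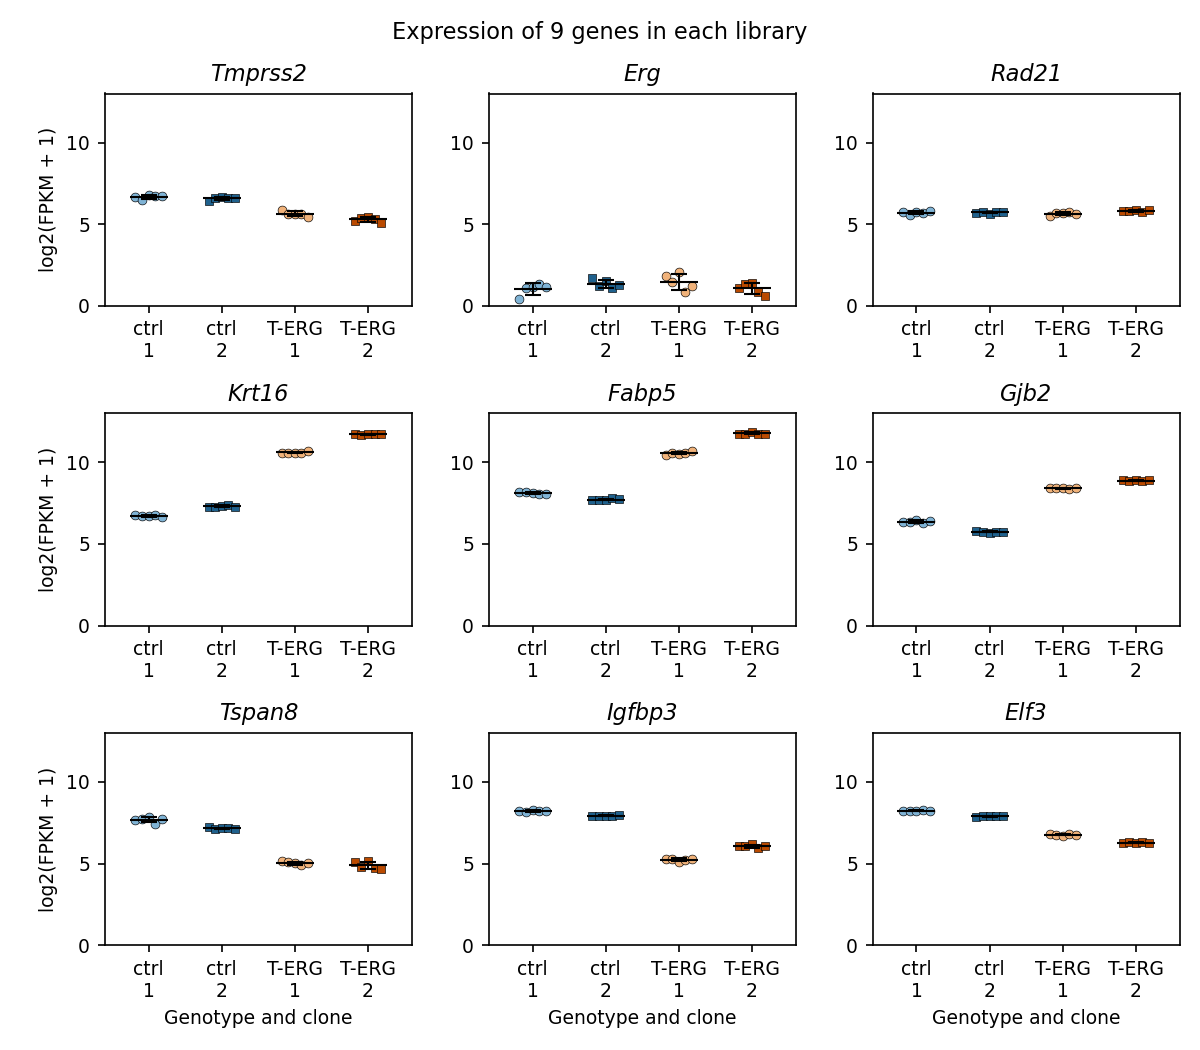
Expression of 9 genes on the log2(FPKM + 1) scale, with 1 point per dome, a horizontal bar at the mean of each clone and error bars of 1 SD over its 5 domes. Krt16 lies near 7 in both control clones and above 10 in both T-ERG clones, while Rad21 lies between 5.65 and 5.81 on average in all 4 clones.

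The median absolute difference over tested genes was 0.24 log2 units between control and T-ERG, each the mean of 2 clones. The other groupings of the 4 clones into 2 and 2 gave 0.20 for clones 1 against clones 2 and 0.14 for control clone 1 and T-ERG clone 2 against the others. Single clones of the same genotype differed by a median of 0.27 in control and 0.23 in T-ERG, which are not on the same footing because a mean of 2 clones varies less than a single clone. Both T-ERG clone means lay above both control means for 2795 genes (21.7%) and below them for 2994 genes (23.2%). In total 44.9% of genes separated by genotype. The shares were 32.5% for clones 1 against clones 2 and 22.6% for control clone 1 and T-ERG clone 2 against the others. A random order of independent clones gives 16.7% in each direction. However, genes vary together over the 4 clones, and nearly every gene separates in 1 of these groupings. Some grouping must then be the largest, so 16.7% is no test of the genotype. All 10 T-ERG libraries lay above all 10 control libraries for 323 genes and below them for 477.

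The 24 genes with the smallest p among those with separate clone means comprised 10 higher and 14 lower in T-ERG, with limma adjusted p between 0.281 and 0.491, and all 20 libraries were separated by genotype for each. Besides Krt16, Fabp5 and Gjb2, the higher genes were Them5, an acyl-CoA thioesterase of mitochondria (4.00 ± 0.23 log2 units, 0.258 to 19.1 FPKM), Endou, an endoribonuclease (5.15 ± 0.57), Alox12b, a lipoxygenase of the epidermal barrier (3.19 ± 0.44), the secreted serine proteases Klk8 (2.96 ± 0.32) and Klk14 (2.45 ± 0.30), Nat8l, which makes N-acetylaspartate (2.66 ± 0.22), and the cytokine gene Il1f9 (2.22 ± 0.30). The kallikreins belong to a family of similar genes, so their values are uncertain to that extent. The lower genes included Slc44a4, a choline transporter-like protein (-2.29 ± 0.28), Pparg, a nuclear receptor of lipid metabolism (-2.10 ± 0.25), Aim2, a sensor of cytosolic DNA (-1.98 ± 0.18), and Mgat3, a glycosyltransferase (-1.96 ± 0.20). Cda, a cytidine deaminase, differed by -1.85 ± 0.26, Enpp5 by -1.68 ± 0.22, Myl7 by -1.67 ± 0.18 and Tspan33 by -1.62 ± 0.21. Sprr2a1, whose near-identical copies make it uncertain, differed by -1.53 ± 0.20, Paqr8, a membrane progestin receptor, by -1.48 ± 0.20, Hsd17b11, a hydroxysteroid dehydrogenase, by -1.39 ± 0.18, and S100a4, a calcium-binding protein, by -1.25 ± 0.14.

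Genes of squamous differentiation, which build the cornified layer of skin, rose as a list in T-ERG (camera adjusted p = 6.33e-07 with the preset correlation, adjusted p = 0.549 with an estimated correlation). The median difference of its 19 tested members was 1.15 log2 units, and 12 members had both T-ERG clone means above both control means, against 1 the other way. Krt6b had 76.0 FPKM in control and 1090 FPKM in T-ERG, Krtdap 179 and 2250 FPKM, and Calm4 46.0 and 496 FPKM. Krt6b is uncertain because Krt6a is nearly identical to it. Ivl, the involucrin gene of the cornified envelope, went the other way, with a difference of -1.67 ± 0.43 log2 units. No member passed over all genes tested, and 8 passed when adjusted over the list alone. The same list also differed between the control clones, with a median of -1.29 and 16 of 19 members called lower in clone 2.

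Markers of luminal cells, the secretory layer of the prostate, fell as a list (camera adjusted p = 1.36e-06, adjusted p = 0.549 with an estimated correlation). Their median was -0.85 over 11 tested members, 9 had both T-ERG clone means below both control means, and 5 passed when adjusted over the list alone, against 0 over all genes. Cldn3, a claudin of tight junctions, had 75.8 FPKM in control and 14.6 FPKM in T-ERG, a difference of -2.29 ± 0.59, and the transcription factors Gata3 and Foxa1 differed by -1.24 ± 0.29 and -0.99 ± 0.27. Between clones the luminal list had a median of 0.20 in control, with 5 members called higher and 3 lower in clone 2, and of -0.35 in T-ERG, with 2 higher and 7 lower. Luminal progenitor markers also fell (camera adjusted p = 6.33e-07, adjusted p = 0.549 with an estimated correlation), with a median of -0.78 over 14 members and 9 of them separate in that direction. Aqp3, a water and glycerol channel, had the largest difference of that list at -1.43 ± 0.66. The progenitor list had a median clone difference of -0.21 in control, with 4 members called higher and 7 lower, and of -0.55 in T-ERG, with 1 higher and 10 lower. Basal markers did not pass (camera adjusted p = 0.729), with a median of -0.01 over 16 members. Krt17, a basal keratin, differed by 1.74 ± 1.01, and Krt14 by 1.27 ± 0.26, while Krt15 differed by -0.96 ± 0.46. Both luminal lists held no member whose T-ERG clone means were both above the control means.

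Androgen receptor targets fell as a list (camera adjusted p = 0.00119, adjusted p = 0.571 with an estimated correlation, and adjusted p = 0.0529 without T-ERG clone 2), with a median of -0.39 over 16 members. Ndrg1 differed by -1.21 ± 0.50 and Sgk1, a kinase induced by steroids, by -1.02 ± 0.31. Of the list, 7 members were separate in the lower direction and 0 in the higher, and 1 passed when adjusted over the list alone. Between the T-ERG clones the list had a median of -0.53, with 12 of 16 members called lower in clone 2, and between the control clones a median of -0.08, with 6 called higher and 6 lower. Interferon response genes fell (camera adjusted p = 8.97e-05, adjusted p = 0.549 with an estimated correlation), with a median of -0.44 over 11 members and 8 separate in the lower direction. The list holds 22 genes, and those left untested reached at most 2.12 FPKM in any library. The camera adjusted p was 0.0161 without a filter on low values and 0.0235 at a mean FPKM of at least 5. Usp18, which trims the ubiquitin-like modifier of that response, differed by -1.67 ± 0.42 and Mx1, an antiviral GTPase, by -1.13 ± 0.24. Hypoxia and glycolysis genes fell (camera adjusted p = 0.000121, adjusted p = 0.549 with an estimated correlation), with a median of -0.54 over 18 members, of which 11 were separate in the lower direction. Bnip3, a mitophagy receptor, differed by -1.70 ± 0.61 and Vegfa, the angiogenic growth factor, by -0.90 ± 0.25. The glucose transporter gene Slc2a1 was the 1 member separate in the higher direction, at 0.65 ± 0.16. Between clones the hypoxia list had a median of 0.20 in control, with 11 members called higher and 4 lower in clone 2, and of -0.35 in T-ERG, with 4 higher and 11 lower. For the interferon list these medians were 0.09 and -0.15, with 4 higher and 1 lower in control and 0 higher and 3 lower in T-ERG.

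Cell cycle genes rose as a list (camera adjusted p = 7.05e-08, adjusted p = 0.591 with an estimated correlation), with a median of 0.89 over 30 members. Mcm5, a subunit of the replicative helicase, had 11.3 FPKM in control and 32.7 FPKM in T-ERG, and Top2a, a topoisomerase of dividing cells, differed by 1.03 ± 0.55. The 2 genotypes overlapped for most members, since 7 had both T-ERG clone means above both control means. Clone 2 had the higher level in each genotype, with a median clone difference of 1.12 in control and 0.97 in T-ERG and 28 of 30 members called higher in both. Genes of MYC and ribosome biogenesis rose (camera adjusted p = 2.37e-07, adjusted p = 0.549 with an estimated correlation), with a median of 0.91 over 17 members, 15 separate in the higher direction and 1, Mycl, in the lower. Gnl3, a nucleolar GTPase, differed by 1.41 ± 0.36, the nucleolar protein gene Nop56 by 1.26 ± 0.45 and Myc by 0.63 ± 0.24. DNA damage signalling and repair genes rose (camera adjusted p = 4.59e-05, adjusted p = 0.685 with an estimated correlation), with a median of 0.45 over 31 members and 9 separate in the higher direction. Between clones of the same genotype its median was 0.51 in control and 0.50 in T-ERG, with 18 and 17 of 31 members called higher in clone 2.

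Mitochondrial transcripts fell as a list by a small amount (camera adjusted p = 0.0438, adjusted p = 0.549 with an estimated correlation), with a median of -0.26 over 13 members and clone medians of -0.15 in control and -0.02 in T-ERG. The member with the largest difference was mt-Co3, at -2.37 ± 1.16, which was below 1 FPKM in 9 of the 20 libraries and between 227.5 and 625 FPKM in the other 11. Without mt-Co3, an alternative chosen after seeing the data, the list had an adjusted p of 0.0879. The adjusted p was 0.0916 without control clone 1, 0.0943 without control clone 2, 0.0872 without T-ERG clone 1 and 0.0273 without T-ERG clone 2. It was 0.105 without a filter on low values, 0.0810 with median centring, 0.0982 without the intensity trend and 0.0565 with all 20 libraries as independent, so the call depended on these choices, while quantile normalization gave 0.00196.

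Cohesin and its regulators did not pass (camera adjusted p = 0.743), with a median of 0.14 over 18 members, 6 separate in each direction. Pttg1, the securin gene, differed by -1.11 ± 0.17 and passed when adjusted over the list alone, and Stag1, a cohesin subunit, by 0.37 ± 0.17. The ETS family did not pass (camera adjusted p = 0.125, adjusted p = 0.549 with an estimated correlation), with a median of -0.15 over 15 members. Its adjusted p was 0.0322 with the clone as a random block, the fit that is not used for calls. Its member with the largest difference was Elf3, an epithelial ETS factor, with 268 FPKM in control and 93.0 FPKM in T-ERG, a difference of -1.53 ± 0.23, and it passed when adjusted over the list alone. Genes reported with ERG in prostate did not pass (camera adjusted p = 0.743), with Plat, the tissue plasminogen activator, at -1.32 ± 0.52. Their median was 0.01 while their mean was -0.16, and camera pointed down. The p53 targets had an adjusted p of 0.111 (0.549 with an estimated correlation), which was 0.0396 without control clone 1 and 0.120 to 0.308 without each other clone, and Tnfrsf10b, a death receptor gene, differed by 0.92 ± 0.45. The oxidative stress list had an adjusted p of 0.192 (0.571 with an estimated correlation), which was 0.0104 without control clone 1 and 0.118 to 0.862 without each other clone, with Gsta1, a glutathione transferase, at 1.32 ± 0.80. The senescence and secretory list did not pass (camera adjusted p = 0.801, adjusted p = 0.932 with an estimated correlation), with Igfbp3 past the threshold when adjusted over the list alone. Without control clone 1 its adjusted p was 0.00481 with camera pointing down, without T-ERG clone 1 it was 0.391 pointing down, and without control clone 2 and T-ERG clone 2 it was 0.0943 and 0.819 pointing up.

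Sterol and fatty acid synthesis genes had an adjusted p of 0.191, with Idi1, an isomerase of the sterol pathway, at 0.40 ± 0.15. Immediate early genes had an adjusted p of 0.392, with the heat shock gene Hspa1a, nearly identical to Hspa1b, at -1.44 ± 0.58. Notch and Wnt components had an adjusted p of 0.719, with the receptor gene Notch1 at 0.90 ± 0.24. Mesenchymal genes had an adjusted p of 0.850 with camera pointing up, while their median was -0.08 and their mean -0.13. Of the lists too small to test, the secretory genes had 2 tested members, with Azgp1 at -0.95 ± 0.28. The fibroblast list had 2, with Dcn at 0.34 ± 0.76, the endothelial list 3, with Egfl7 at 0.43 ± 0.46, the immune list 2, with Cd68 at -0.64 ± 0.27, and the neuroendocrine list 0.

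**Figure D3:**
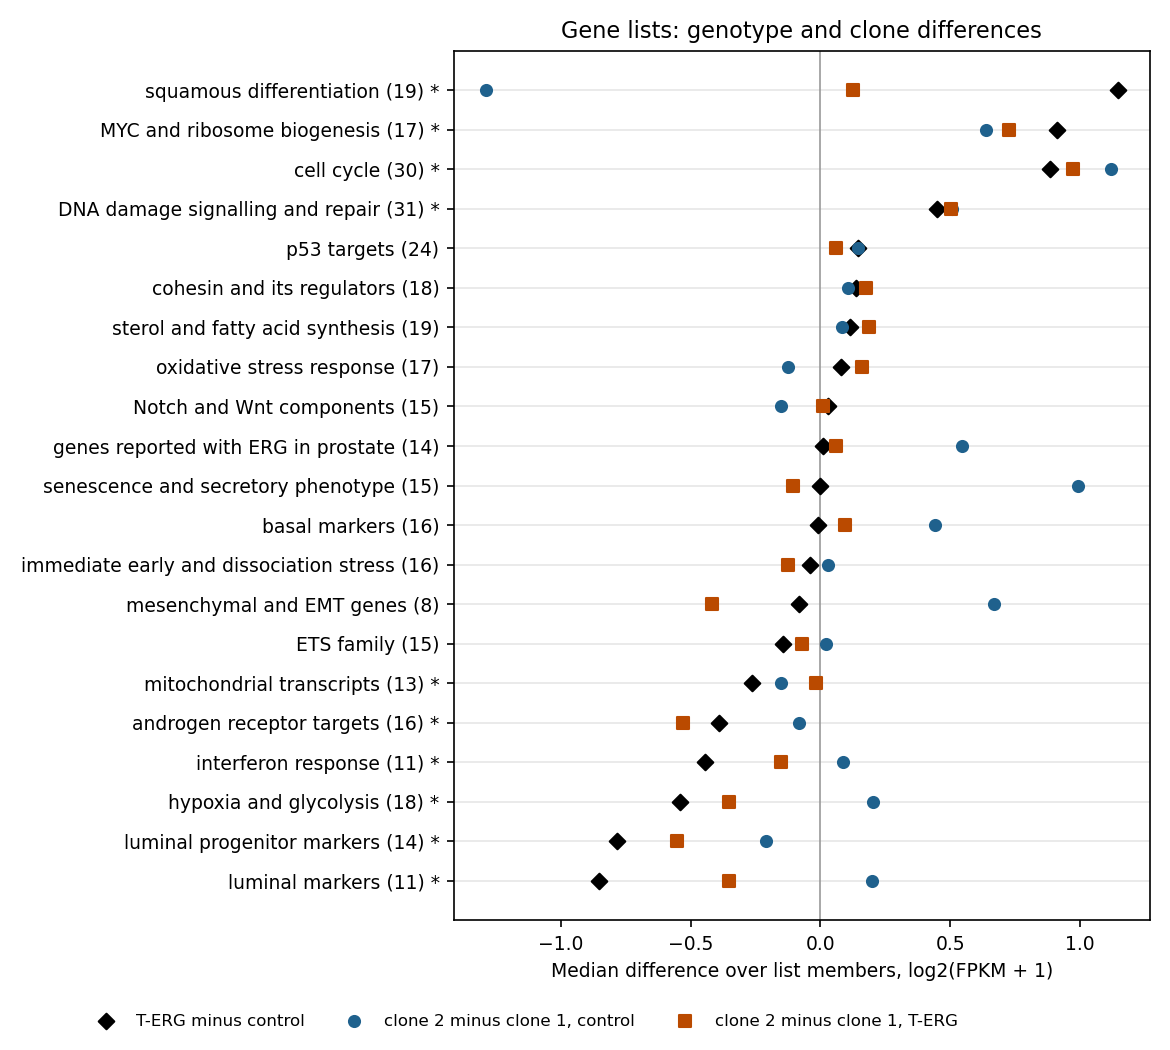
Median difference over the members of each of 21 gene lists on the log2(FPKM + 1) scale, for T-ERG minus control (diamonds) and for clone 2 minus clone 1 in control (circles) and in T-ERG (squares). The number of tested members is in parentheses and an asterisk marks a camera adjusted p under 0.05 with the preset correlation, and the squamous list lies at 1.15 between genotypes and -1.29 between the control clones.

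The clones of 1 genotype were compared to measure how far separate cultures of it lie apart, and the p-values compare these cultures, not a condition. In control, the squamous differentiation list had 16 of 19 members called lower in clone 2. Cnfn, a cornified envelope gene, fell by 5.24 ± 0.29 log2 units, from 123 to 2.60 FPKM, Rptn, the repetin gene of the same envelope, by 4.98 ± 0.07, and Krt1, a keratin of the upper epidermis, by 3.79 ± 0.05. Ltf, the iron-binding lactoferrin, rose by 5.39 ± 0.20, from 2.59 to 146 FPKM, and the neutrophil-attracting chemokine genes Cxcl3, Cxcl5 and Cxcl1 rose by 5.01 ± 0.20, 4.75 ± 0.09 and 3.73 ± 0.19. The senescence and secretory list, which holds such chemokines, had 13 of 15 members called higher in control clone 2. The limma test on 5 against 5 libraries called 4939 of 12899 genes (38.3%), 3233 higher and 1706 lower in clone 2. The median over all genes was 0.10 log2 units in favour of clone 2, and after quantile normalization, which removes it, 2354 genes were called higher and 2295 lower.

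In T-ERG, clone 2 had lower Wfdc18, a whey acidic protein gene, listed at 0 in clone 2 and at a mean of 87.4 FPKM in clone 1. Arg1, the arginase of the urea cycle, fell by 3.67 ± 0.08 log2 units, from 304 to 23.0 FPKM, Plac8 by 3.43 ± 0.08, from 413 to 37.5 FPKM, and Col8a1, a collagen gene, by 4.50 ± 0.11. Tceal8 rose by 4.72 ± 0.24, from 0.484 to 36.5 FPKM, Stfa3, a protease inhibitor of the stefin family with similar copies, by 3.04 ± 0.27, and S100a9, a calcium-binding protein of inflamed epithelium, by 2.52 ± 0.17. The X-linked gene Xlr3a, which has near-identical copies, and the meiosis gene Tex11 were listed at a mean of 0 in clone 1 and at 10.7 and 8.86 FPKM in clone 2. The limma test called 3934 of 12899 genes (30.5%), 2199 higher and 1735 lower in clone 2. These were 2020 and 1861 after quantile normalization and 1847 and 2019 after median centring, so the more frequent direction depended on the scaling.

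The clone differences of both genotypes shared 2293 called genes, where independent lists of these sizes would share 1506 if every gene were equally likely to be called. Calls were more frequent at a mean FPKM of 5 or more than below it, at 43.9% against 24.9% in control and 35.5% against 18.6% in T-ERG. Part of the overlap above 1506 is therefore built in. Of the 2293 shared genes, 1710 (74.6%) went the same way. Cell cycle genes were among those that did, and of the MYC and ribosome biogenesis list 15 of 17 members were called higher in clone 2 in each genotype, with medians of 0.64 in control and 0.73 in T-ERG. The clone numbers are names given by the submitters, and no source used here ties clone 2 of control to clone 2 of T-ERG.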

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

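Among the tests in this part, the split count of the genotype comparison and the test of a culture state were chosen only after the result was seen. Across the 4 clones, 216 sets of 5 domes were examined for a single dome far from the other 4, and 15 were found, where chance gives about 10.8. The following values are on the log2(FPKM + 1) scale. In control clone 1, Erg was at 0.40 in replicate 1 against 1.10 to 1.33 in the other domes, Ndrg1 at 6.37 in replicate 1 against 6.19 to 6.23, Pttg1 at 6.17 in replicate 5 against 5.90 to 5.97, and Tnfrsf10b at 2.35 in replicate 5 against 2.09 to 2.15. In control clone 2, Endou was at 0.18 in replicate 8 and Klk14 at 0.34 in replicate 6, each against 0 in the other domes, and Idi1 was at 7.09 in replicate 8 against 7.20 to 7.22. In T-ERG clone 1, replicate 5 had Krt16 at 10.67 against 10.57 to 10.59 and Sprr2a1 at 5.78 against 6.23 to 6.29. In T-ERG clone 2, Fabp5 was at 11.87 in replicate 10 against 11.73 to 11.76. In the same clone, unnumbered library b had Azgp1 at 0.34 against 0, Dcn at 1.27 against 0.38 to 0.62, and Cd68 at 0.74 against 2.59 to 2.78. For mt-Co3, replicate 9 of control clone 2 was at 0.16 against 7.84 to 9.10, and replicate 10 of T-ERG clone 2 was at 9.10 against 0.23 in each of the other 4 domes.

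Squamous differentiation genes were higher in both T-ERG clones for 12 of 19 tested members, with a median difference of 1.15 log2 units. The tables argue against scaling between libraries, since the median under quantile normalization was 0.933 of its deposited-scale value. A lower share of luminal cells would raise squamous and basal markers alike and stays open, because the squamous median lay 1.16 above the basal median (95% bootstrap interval over genes 0.46 to 2.73), but the same gap was -1.73 between the control clones, so it was not beyond the spread between clones. A culture state that also varies between clones of 1 genotype stays open, since the list differed by -1.29 between the control clones and by 0.13 between the T-ERG clones, while the correlation across genes of genotype and clone differences (r of at least 0.248) decides nothing, because both are built from the same clone means and 1 outlying clone makes them correlate. With 2 clones per genotype such a state cannot be told apart for these genes from the ERG genotype, the difference that the design names, and both this and a larger share of squamous cells stay open and untested.

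Tmprss2 was lower in all 10 T-ERG libraries, by 1.17 log2 units on average, without passing the threshold. Scaling between libraries left it in place, as the difference under quantile normalization was 1.02 times its deposited-scale value. A general fall of androgen receptor targets and luminal genes stays open, because although the median of the 24 other members of those lists (-0.47) lay 0.695 above the difference of Tmprss2, 3 of the 24 (Cldn3, Gata3 and Ndrg1) lay below it, so that a gap to the median excludes nothing for a single gene. The name of the control genotype also holds Tmprss2 and ERG, so its locus may be engineered too. As a further hypothesis, the Tmprss2 locus of T-ERG may yield less transcript that is counted as Tmprss2. Reads per exon, which would bear on this, were not analysed here.

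Many genes differed between clones of 1 genotype, 4939 in control and 3934 in T-ERG. Of 100 splits of the 10 libraries of each genotype into 5 and 5, only the real one gave as many genes. The highest of the others gave 3 in control and 4 in T-ERG. Random divisions of these domes thus did not give such counts, which describe a difference between these cultures. The other splits mix domes of both clones, so the clone gap adds to their error and lowers their counts. A whole-chromosome copy number difference was not seen, since the largest absolute median clone difference of any autosome was 0.14 log2 units. The estimated relative depth differed by 1.05 times between the clones in control and by 1.01 times in T-ERG. The share of called genes was at least 16.9 percentage points higher at a mean FPKM of 5 or more than below it. This gap decides nothing on depth, because differences are easier to call in genes at higher levels. Smaller copy number changes, the passage or day of culture and the animal of origin stay open and were not tested. For the genotype comparison, all 3 splits of the 4 clones gave 0 genes, an outcome of no weight because a real count of 0 is matched by any split, and 3 splits are too few for a share under 0.05.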

How the results depend on the processing

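The comparison without a block on the 6 numbered T-ERG domes and the mitochondrial list without mt-Co3 were chosen after seeing the data. The 0 genes of the genotype comparison stayed 0 under other filters, pseudocounts, scalings and variance priors, with the clone number as a block, and without each clone. Against that, 1398 genes were called with the clone as a random block, 4737 with all 20 libraries as independent, and 4170 with the title number as a replicate block on 16 libraries, fits in which domes count as replicates. Of the 50 named genes, 41, 44 and 43 passed in these fits and 0 in the others. The 10 lists called became 0 with estimated correlations. The count stayed between 9 and 12 elsewhere, but those settings kept the preset correlation between genes and so did not test it. Among the lists called, the estimated correlation ran from 0.163 (interferon response) to 0.965 (cell cycle), above the preset value. The exception was the mitochondrial list, at -0.0475. For variance priors, the random block, the clone block and left-out clones, lists were tested on the moderated statistics of each fit.

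The clone difference stayed between 4079 and 4932 genes in control, including 4539 to 4820 without each library. In T-ERG it stayed between 3368 and 3936, including 3513 to 3797 without each library, except that the dome number as a replicate block gave 1370 genes and the same 6 libraries without a block 2250. The fewer libraries thus account for part of the lower count. Libraries sharing a number were not treated as pairs, since no label ties them and no title or dome correlation was over 0.1. Deviations of domes with the same title number correlated at -0.06 to 0.09, with 1 of 8 control libraries closest to its own number. Dome numbers correlated at 0.009 to 0.06 in control, where 4 of 5 were closest to their own number, and at -0.007 to 0.05 in T-ERG, where 2 of 3 were, a hint that dome numbers share something. With the dome block, 4510 genes were called in control. Clone numbers correlated at 0.17 over only 2 pairs, and their block called 0 genes.

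Some results that had not passed changed direction, and the cause was not tested. Leaving out a clone assumes that the lone clone left varies like the others. In signed adjusted p (negative for down), the cohesin list was -0.615 with the stricter filter and ranged from -0.580 to 0.804 without each clone, and the mesenchymal list was -0.788 with the random block and ranged from -0.318 to 0.221. The senescence list was 0.850 with the clone block and 0.462 with the title block and ranged from -0.391 to 0.819 (-0.00481 without control clone 1). The basal list ranged from -0.441 to 0.664 and the genes reported with ERG from -0.899 to 0.753. Log2 differences without each clone ranged from -0.12 to 0.29 for Erg, -0.47 to 1.15 for Dcn and -0.18 to 1.05 for Egfl7. The Rad21 log2 difference ranged from -0.0643 to 0.0922 and was -0.00585 with the title block. Absolute depth is unknown, so no floor can be given for genes listed at 0.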

Other observations

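Genes with all 20 libraries separated by genotype, beyond those already named and chosen here after their values were seen, included Slc16a3, Clca1, Adh1 and Fabp4. Slc16a3, a lactate exporter, had 37.2 and 19.7 FPKM in the control clones, 1.93 FPKM in T-ERG clone 1 and was listed at 0 in T-ERG clone 2. Clca1, a secreted regulator of mucus and chloride channels, had 1318 and 270.3 FPKM in the control clones and 172 and 32.0 FPKM in the T-ERG clones, so its clone differences of -2.28 in control and -2.39 in T-ERG were nearly as large as its genotype difference of -2.99 ± 1.09 log2 units. Adh1, an alcohol dehydrogenase of retinol metabolism, had 14.2 FPKM in control and 0.755 FPKM in T-ERG, and Fabp4, a fatty acid-binding protein of adipocytes, 1.43 and 18.3 FPKM. In limma on clone means the adjusted p of these 4 genes lay between 0.506 and 0.574.

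Some genes of differentiated prostate secretory cells were listed at 0 in both genotypes. Pbsn and Msmb, which encode secreted proteins of the prostate, were listed at 0 in all 20 libraries. An exact 0 in this table can be a failed estimate.

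The mitochondrial gene mt-Co3 alternated between domes of the same clone. It was between 0.05 and 0.17 FPKM in 2 domes of control clone 1, 1 of control clone 2, 2 of T-ERG clone 1 and 4 of T-ERG clone 2, and at 227.5 FPKM or more in the other 11 libraries. Over the whole table, 117 genes reached 50 FPKM in at least 1 dome of a clone while another dome of that clone lay below 1% of the highest, and 2 of these were protein-coding, mt-Co3 and Defb14. In all 4 clones this was so for 12 genes, of which mt-Co3 was the 1 protein-coding gene.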
